A study of Bifidobacterium breve UCC2003 with 8 samples.

How the data were processed

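Bifidobacterium breve UCC2003, a human-derived gut bacterium, was grown without oxygen in modified MRS medium with 0.05% (w/v) cysteine and 1% (w/v) of a single sugar as carbon source, per the labels' protocols. The carbon source was kojibiose, 4-galactosyl-kojibiose, lactulose, lactulosucrose or ribose. Cells were collected at an optical density of 0.5. RNA from cells grown on a sugar and RNA from cells grown on ribose were labelled with different dyes and hybridised to the same Agilent array. There were 8 arrays, 2 biological replicates for each of the 4 sugars. Per the labels, the sugar RNA carried Cy3 on the replicate 1 array and Cy5 on the replicate 2 array, so the replicate number and the dye orientation cannot be separated. The 2 kojibiose and 2 4-galactosyl-kojibiose arrays were on slide 1, and the lactulose and lactulosucrose arrays were on slide 2, and the slides were scanned separately. Slide and sugar pair therefore cannot be told apart in a difference between sugars of different slides, although each array carries its own ribose channel. The labels do not say whether arrays shared ribose RNA. If they did, the spread between ribose cultures is missing from the errors.

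The scanner files hold intensity values, the mean brightness of each spot and the median brightness of its local background in both channels, as the authors deposited them. They also hold log10 ratios of Cy5 over Cy3. Per the file headers, these log10 ratios were made by Feature Extraction after detrending, background estimation and a LOWESS dye normalisation, with the background correction step switched off. The submitters' processing notes name Feature Extraction 9.5, while the file headers name version 9.1.1.1 for the steps. A deposited table for each sugar holds 2 columns of log10 ratios. Each column equals the log10 ratio of one scanner file spot by spot, within 1.11e-16, so its scale, centring and direction are those of the scanner files, although one column of each pair is headed as an inverse. The medians of these columns lay between -0.0077 and 0.00863. Per the design text, the study called genes by a regularised t-test, Cyber-T, at a p limit of 0.001 and a ratio above 3 or below 0.33.

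Each array held 45220 spots, of which 43142 carried a probe for a Bbr locus tag. There were 8137 such probes, each printed on 5 or 6 spots, and 1843 genes with 1 to 30 probes (median 3). Here the background was corrected by normexp with an offset of 50, fitted on all spots, and each array was normalised within itself by loess with control spots and spots with outlier flags at weight 0 (limma 3.58.1 in R 4.3.3, files read with the data.table package at version 1.17.8, figures drawn in Python 3.11.15). The same spots were then left out, and saturated spots were kept. Every log2 ratio was turned so that the sugar is the numerator. Spots of a probe were averaged, and a gene's log2 ratio is the median over its probes. No arrays were scaled to each other.

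The number of arrays limits the precision of every value. Median sugar-channel signals were 5.61 and 12.0 times the median of the 153 negative control spots on the kojibiose arrays, and between 1.42 and 2.29 times on the other 6 arrays. The ribose channel lay between 1.71 and 3.91 times its negative controls. A gene was called not well above background in a channel when none of its probes passed Feature Extraction's own test on at least 50% of their spots, and such a gene has only a bound when this held on both arrays of a sugar. That bound sets the mean normalised level of the bright channel against the lowest level of a probe well above background in the dim channel (or the dim gene's own level, if higher), after loess and Aquantile. With 4-galactosyl-kojibiose 375 genes were not well above background in the sugar channel alone, against 93 for lactulose, 2 for lactulosucrose and 0 for kojibiose.

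Sugar and ribose were compared in limma (lmFit and eBayes) over all 8 arrays with 1 mean per sugar, so that 4 residual and 3.02 prior degrees of freedom were shared between the sugars. The Benjamini-Hochberg adjustment ran over the 1843 genes, and an adjusted p under 0.05 was called. Genes that were also over 3-fold are counted separately. Differences between sugars were contrasts of the same fit. Pooling matters because the median SD between the 2 replicates of a gene was 0.102 for kojibiose, 0.0866 for 4-galactosyl-kojibiose, 0.226 for lactulose and 0.252 for lactulosucrose (log2). The replicates of a sugar correlated across genes at 0.929, 0.966, 0.843 and 0.686 in that order, and no spot was identical on any pair. The labels call the replicates biological and do not say more about their cultures.

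Arrays with the same replicate number deviated together from their sugars' means in all 6 pairs of sugars, with correlations across genes between 0.451 and 0.837. The pairing comes from the labels' replicate numbers and is confounded with the dye. A fit with the replicate number as a term, in which 268 genes had a called replicate effect, is given beside a result where it changes the call or moves a count by over 1.5 times.

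Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and all alternatives. The scanner files give locus tags without gene names, and the reference table used here is for another strain, in which 0 tags matched. The 19 lists that needed a gene name or product therefore could not be filled and are not reported. The 6 lists defined by a range of locus tags were used, and 4 of them had at least 5 measured genes and were tested with camera, at a preset correlation of 0.01 and with an estimated one. What these tag ranges encode is background knowledge about this strain, not information from the files, and their limits may differ from the operons. The rule named, for each sugar, the called genes with the largest rises and falls in the same direction on both arrays, up to 3 members of each list passing or not, and for each pair of sugars the largest called differences. All members of the tag ranges were open to naming. Because other tags have no gene name here, the text names at most 2 rising and 2 falling tags per comparison outside the ranges, apart from features singled out after their values were seen.

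The test was checked on simulated ratios drawn for the 1843 genes with their fitted spreads, with 100 genes changed at each of 2 sizes. The arrays were drawn independently, without the deviation that same-numbered arrays share, so the percentages leave this pairing out. Each gene had the same pooled spread on all arrays. The percentages against ribose therefore differ between sugars only by the random draw. They leave out the larger spread between replicates of lactulose and lactulosucrose. Against ribose, a log2 change of 1 was called in 94% (kojibiose), 92% (4-galactosyl-kojibiose), 96% (lactulose) and 97% (lactulosucrose) of the changed genes, and unchanged genes in 0.611%, 0.916%, 0.672% and 0.672%. A log2 difference of 1 was called in 74% of genes for 4-galactosyl-kojibiose against kojibiose and in 72% for lactulosucrose against lactulose. Alternatives were no background correction, an offset of 16, the Feature Extraction ratios, median centring in place of loess, scaling between arrays, the mean over probes, a filter on dim genes, an intensity trend, the replicate term, the arrays of 1 slide or of 1 sugar, an adjusted p limit of 0.01, the study's regularised t-test and leaving out each array. The filter on dim genes kept 1842 of the 1843 genes, so it cannot show how the results depend on dim genes. The deposited tables hold no p-values, so an alternative based on those was not run. Where 1 array of a sugar was left out, the other was assumed to vary like those of the other sugars. That sugar then added nothing to the pooled spread. In comparisons without that sugar, leaving out either of its arrays therefore gave the same result. Their log2 values stayed as they were, and only the pooled spread and its degrees of freedom changed.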

Results

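Gene expression of B. breve UCC2003 was measured on 8 two-colour arrays, each comparing cells grown on 1 of 4 sugars with cells grown on ribose. Kojibiose is a disaccharide of glucose, and 4-galactosyl-kojibiose carries an added galactosyl residue. Lactulose is a disaccharide of galactose and fructose, and lactulosucrose carries an added glucosyl residue. The series title gives the purpose as the metabolism of biosynthetic oligosaccharides. It also names a Bifidobacterium longum strain, which was not analysed here. Each sugar had 2 biological replicates, and 1843 genes were measured on every array. The share of gene spots well above background in the sugar channel was 99.99% on both kojibiose arrays, 61.4% and 47.7% with 4-galactosyl-kojibiose, 65.7% and 67.0% with lactulose, and 89.8% and 73.5% with lactulosucrose. In the ribose channel it lay between 53.7% and 99.8%. Values below are log2 ratios of sugar over ribose, given with the SE from limma at n = 2 arrays unless another n is stated. This SE pools the spread over all 8 arrays, so a gene has the same SE with every sugar. It can be too small for lactulose and lactulosucrose, whose replicates differed more. Genes are named by locus tag because the files pair no tag with a gene name.

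Growth on any of the 4 sugars in place of ribose changed a large part of the transcriptome. The largest shared response was a fall of the neighbouring genes Bbr_1415 to Bbr_1419, which were over 3-fold lower with all 4 sugars. In all, 97 genes were higher and 126 genes lower with all 4 sugars, 9 and 5 of them over 3-fold. Over 3-fold higher in all 4 were Bbr_0530 of the gos locus and Bbr_0027 of the fructo-oligosaccharide locus, with 7 genes outside the loci. The falls of Bbr_1415 to Bbr_1419 were larger on replicate 1 than on replicate 2 with every sugar, and Bbr_1415, Bbr_1416, Bbr_1417 and Bbr_1419 were among the genes that deviated most between replicate numbers, and so between dye orientations, over the 4 sugars. Leaving out an array of a sugar can move their fold by over 1.5 times. Bbr_1419 with lactulosucrose, for example, was at -3.13 without replicate 1 and at -4.94 without replicate 2.

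By limma, 699 genes changed with kojibiose (342 higher, 357 lower), 643 with 4-galactosyl-kojibiose (340 higher, 303 lower), 1029 with lactulose (471 higher, 558 lower) and 559 with lactulosucrose (257 higher, 302 lower). Over 3-fold were 44, 88, 98 and 50 genes in that order. Rises outnumbered falls over 3-fold with 4-galactosyl-kojibiose (79 against 9), lactulosucrose (44 against 6) and kojibiose (30 against 14), and with lactulose falls outnumbered rises (59 against 39). Several of these splits turned in other settings. With the Feature Extraction ratios 4-galactosyl-kojibiose had 286 genes higher and 378 lower. Lactulosucrose had 241 higher and 201 lower without its replicate 1, and 132 higher and 99 lower on slide 2 alone. Kojibiose had 520 higher and 480 lower with the replicate number in the fit. Without lactulose replicate 1 the lactulose genes over 3-fold were 42 higher and 38 lower. The few falls over 3-fold also depended on the setting. The Feature Extraction ratios gave 109 higher and 59 lower with 4-galactosyl-kojibiose and 92 higher and 67 lower with lactulosucrose, which had 42 higher and 24 lower without its replicate 2. After median centring the kojibiose genes over 3-fold were 6 higher and 109 lower, and without background correction those with lactulose were 27 higher and 17 lower. The counts use a spread pooled over slides. Within a slide they were 1170 (kojibiose), 1042 (4-galactosyl-kojibiose), 604 (lactulose) and 231 (lactulosucrose), so the order of the sugars is not the same. With the replicate number in the fit lactulosucrose had 888 genes. Kojibiose fell to 196 genes without its replicate 1 and 200 without its replicate 2, 4-galactosyl-kojibiose to 239 and 320, and lactulose to 579 without its replicate 1. Without lactulose replicate 2, 153 genes were over 3-fold with lactulose.

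**Figure D1:**
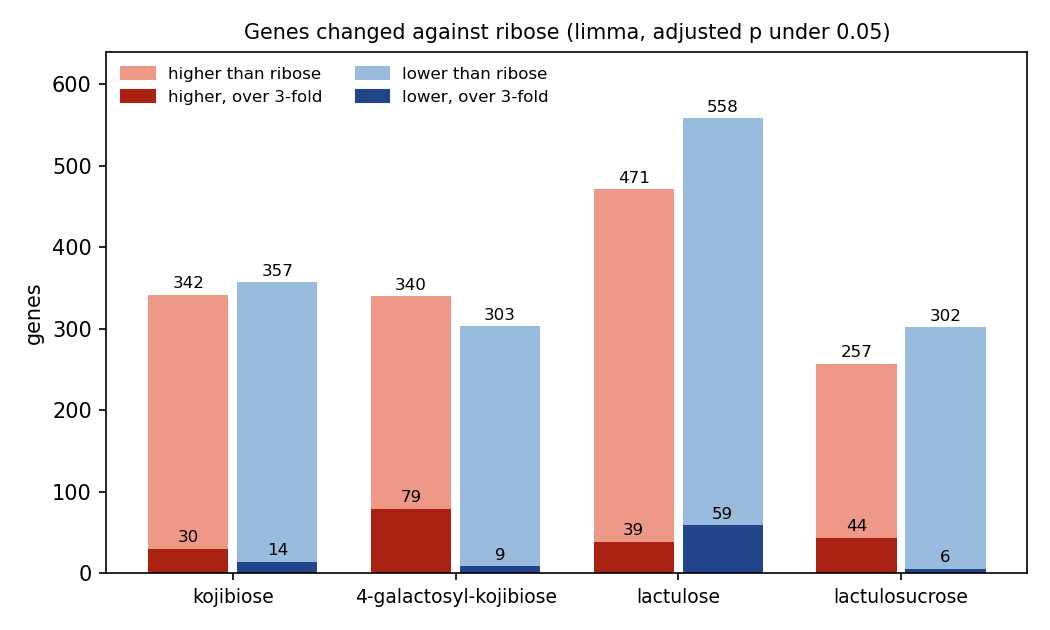
Number of genes higher or lower than on ribose with each of the 4 sugars (limma over 8 arrays), with the genes over 3-fold in the darker part of each bar. Lactulose had the most genes past the test (1029) and lactulosucrose the fewest (559) with the pooled spread.

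The kojibiose comparison asks which genes respond to this glucose disaccharide. Kojibiose raised Bbr_1774 and Bbr_0433 more than 8-fold, which 4-galactosyl-kojibiose did not. It lowered Bbr_1417 to Bbr_1419 in the range chosen for ribose use and raised most of the 15 genes Bbr_1855 to Bbr_1869, a neighbourhood of alpha-glucosidase and raffinose loci. In the lactose range Bbr_1551 to Bbr_1553 1 of 3 genes rose. Bbr_1774 rose by 3.14 ± 0.19 (8.84-fold, adjusted p 0.000194) and Bbr_0433 by 3.13 ± 0.17 (8.76-fold, adjusted p 0.000179), and each call held in every alternative run. With 4-galactosyl-kojibiose these genes stood at -0.50 (adjusted p 0.0873, and 0.0407 with the replicate number in the fit) and -0.50 (0.0544, and 0.0148). Bbr_1418 fell by 3.98 ± 0.38 (15.8-fold lower, adjusted p 0.000568) and Bbr_1417 fell by 3.71 ± 0.47 (13.1-fold lower). Bbr_1419, at -3.21, and its neighbours Bbr_1416 (-2.84) and Bbr_1415 (-2.80) lost their calls without kojibiose replicate 1 (adjusted p 0.0775, 0.0937 and 0.0556), and the calls of Bbr_1419 and Bbr_1416 were also lost with the Feature Extraction ratios (0.0516 and 0.0818).

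Among Bbr_1855 to Bbr_1869, 12 of 15 genes rose with kojibiose (14 adjusted over the list alone), led by Bbr_1865 at 1.54 ± 0.21 and Bbr_1866 at 1.34 ± 0.12 (2.53-fold, adjusted p 0.00047). Those 2 calls were lost with the Feature Extraction ratios (adjusted p 0.283 and 0.0936). Several of the others lost their calls without 1 kojibiose array, Bbr_1861 for example without replicate 1 (0.134) and replicate 2 (0.268). In the gos locus, Bbr_0526 to Bbr_0530, 4 of 5 genes rose (4 adjusted over the list alone). Bbr_0530 rose by 1.75 ± 0.11 (3.37-fold, adjusted p 0.000194) and Bbr_0529 was at 0.02 (0.906). After median centring Bbr_0527, at 0.88, turned to -0.11, and Bbr_0528, at 0.73, turned to -0.09. Bbr_0528 also lost its call without kojibiose replicate 1 (adjusted p 0.111) or 2 (0.0883), as did Bbr_0526, at 0.49 (0.262 and 0.191, and 0.0633 without either 4-galactosyl-kojibiose array). In the fructo-oligosaccharide range, of which 3 of 5 tags were measured, Bbr_0027 rose by 2.23 ± 0.17 (4.70-fold) and Bbr_0026 by 1.46 ± 0.21, the latter lost without kojibiose replicate 1 (0.0508). Of the 3 lactose-range genes only Bbr_1553 passed (0.43, adjusted p 0.0173), not without kojibiose replicate 1 (0.206) or 2 (0.118), and Bbr_1552, at 0.34 (0.306), passed with the replicate number in the fit (0.0334).

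4-Galactosyl-kojibiose raised the neighbouring genes Bbr_1832 to Bbr_1836 by more than 4 log2 units, and far less was seen with the other sugars. It also raised Bbr_1552 of the lactose range 25-fold and all 5 genes of the gos locus. The ribose range again held large falls. Bbr_1836 rose by 5.09 ± 0.13 (34.0-fold, adjusted p 1.81e-06) and Bbr_1832 by 4.98 ± 0.17 (31.6-fold, adjusted p 3.73e-06). The lowest of the 10 log2 ratios of Bbr_1832 to Bbr_1836 was 4.05. Bbr_1831 beside them was over 3-fold higher too, but rose less than any of these. With the other sugars Bbr_1836 stood at 0.87 (kojibiose), 0.50 (lactulose) and 0.29 (lactulosucrose). Bbr_1552 rose by 4.64 ± 0.24 (25.0-fold, adjusted p 1.9e-05) and Bbr_1551 by 2.82 ± 0.33 (7.07-fold). On replicate 2 the ribose channel of Bbr_1832 to Bbr_1836, Bbr_1551, Bbr_1552 and Bbr_1866 was not well above background, so these folds rest on a dim channel in 1 of 2 arrays. On replicate 1, where it was, Bbr_1836 stood at 5.28, Bbr_1552 at 4.87 and Bbr_1551 at 3.00. Bbr_0530 rose by 2.75 ± 0.11 (6.74-fold, adjusted p 5.18e-06), Bbr_0529 by 1.36 and Bbr_0527 by 1.32. Bbr_0027 rose by 4.04 ± 0.17 (16.4-fold) and Bbr_1866 by 2.26 ± 0.12 (4.81-fold). Bbr_1418 fell by 3.67 ± 0.38 (12.7-fold lower, adjusted p 0.000406) and Bbr_1419 fell by 3.25 ± 0.53, the latter lost without 4-galactosyl-kojibiose replicate 1 (0.0614). In this comparison 375 genes were not well above background in the sugar channel alone, and 48 of these were called.

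Lactulose moved the most genes with the pooled spread, more of them down than up. All 5 gos genes rose. Its largest rises outside the ranges were Bbr_1880 and Bbr_0625. Of these, Bbr_1880 was over 3-fold higher with all 4 sugars, at 2.53 with kojibiose and 3.81 with 4-galactosyl-kojibiose. The ribose range again held large falls, as with kojibiose. Bbr_1880 rose by 3.00 ± 0.19 (8.00-fold, adjusted p 6.99e-05) and Bbr_0625 by 2.89 ± 0.26 (7.40-fold, adjusted p 0.000214). Bbr_1419 fell by 4.25 ± 0.53 (adjusted p 0.000717) and Bbr_1417 fell by 4.16 ± 0.47 (17.9-fold lower). Bbr_0530 rose by 1.77 ± 0.11 (3.41-fold, adjusted p 6.1e-05), and the other 4 gos genes rose by between 0.64 and 0.81. Each of those 4 lost its call in some setting. Bbr_0527 did after median centring (0.0977) and after scaling between arrays (0.098), as did Bbr_0529 (0.0684 and 0.0636). Without lactulose replicate 1, Bbr_0526 (0.0876) and Bbr_0528 (0.105) did. Bbr_1552 rose by 1.98 ± 0.24 (3.94-fold), and Bbr_1551, at 0.90, did not pass (adjusted p 0.0507), but did with the replicate number in the fit (0.000765), without lactulose replicate 2 (0.0241) and without either lactulosucrose array (0.022). Bbr_0027 rose by 2.19 ± 0.17 (4.56-fold). In the alpha-glucosidase and raffinose range, 7 of 15 genes rose, and the sugar channel of Bbr_1866 was not well above background. With lactulose 93 genes were not well above background in the sugar channel alone, and 42 of these were called. Another 3 called genes were not well above background in either channel. Of the genes over 3-fold, 4 were not well above background in at least 1 channel.

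Lactulosucrose raised all 5 gos genes and the genes Bbr_1865 to Bbr_1867. It raised Bbr_1880 and Bbr_0285 most among genes outside the ranges, although Bbr_1880 was over 3-fold higher with every sugar. Bbr_1417 to Bbr_1419 fell as with the other sugars. Bbr_1880 rose by 3.29 ± 0.19 (9.79-fold, adjusted p 6.95e-05) and Bbr_0285 by 3.01 ± 0.13 (8.06-fold, adjusted p 2.73e-05). Bbr_1866 was at least 8.73-fold higher (adjusted p 1.93e-05), a bound because its ribose channel was not well above background. Bbr_1867 rose by 2.96 ± 0.21 (7.78-fold) and Bbr_1865 by 2.70 ± 0.21 (6.50-fold). The ribose channel of Bbr_0285, Bbr_1867 and Bbr_1865 was not well above background on replicate 1. Bbr_0530 rose by 2.41 ± 0.11 (5.30-fold, adjusted p 2.73e-05), Bbr_0528 by 1.74, Bbr_0529 by 1.67 and Bbr_0527 by 1.59. Bbr_1552 rose by 3.40 ± 0.24 (10.6-fold, adjusted p 0.000149) and Bbr_1551 by 2.37 ± 0.33 (5.18-fold). In the galactan range Bbr_0417 to Bbr_0422, Bbr_0419 rose by 1.77 (3.40-fold) and Bbr_0418 by 1.58 (2.98-fold, adjusted p 9.14e-05). Bbr_1419 fell by 4.03 ± 0.53 (16.4-fold lower) and Bbr_1417 fell by 3.97 ± 0.47 (15.7-fold lower).

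Taken as whole lists against the other genes (camera at the preset correlation), 14 of 16 list tests against ribose passed, and with an estimated correlation only the gos shift with lactulosucrose did (adjusted p 1.01e-05, and 0.0342 with the estimate). For the gos locus the adjusted p were 0.0115 with kojibiose, 0.000266 with 4-galactosyl-kojibiose and 0.00641 with lactulose, against 0.0958, 0.0605 and 0.129 with the estimated correlation. The estimate for this locus was -0.0087, below the preset 0.01, so a higher correlation did not raise its p. The preset and estimated forms of camera thus differ in more than the correlation. For the other ranges the estimates were above the preset, at 0.588 (galactan), 0.163 (ribose) and 0.052 (Bbr_1855 to Bbr_1869). Their p at the preset correlation can therefore be too small. The range Bbr_1855 to Bbr_1869 shifted up with every sugar (1.07e-05, 0.0153, 0.0085 and 0.000106 in the order of the sugars), against 0.0745, 0.191, 0.161 and 0.0602. The galactan range shifted up with kojibiose (0.0301), 4-galactosyl-kojibiose (0.0183) and lactulosucrose (0.00156), against 0.309, 0.361 and 0.177, and missed with lactulose (0.0582), where it passed without lactulose replicate 2 (0.0166) or either lactulosucrose array (0.0443). The ribose range shifted down with kojibiose (0.0301), lactulose (0.0198) and lactulosucrose (0.0003), against 0.249, 0.198 and 0.0714, and missed with 4-galactosyl-kojibiose (0.247), where its median was -0.02 and its mean -1.36. Genes past the test, adjusted over the list alone, numbered 5 of 5 in the gos locus with each sugar but kojibiose (4). In the galactan range they numbered 3 (kojibiose), 3, 2 and 3 of 6, all higher, and with the replicate number in the fit 4, 4, 4 and 5 passed over all genes. In the ribose range 5 genes fell and 1 rose with kojibiose, and 3, 4 and 6 of 7 fell with the others. In the range Bbr_1855 to Bbr_1869 they numbered 14, 6, 7 and 6 of 15, all higher. In the lactose range they were 1, 3, 3 and 3 of 3, and in the fructo-oligosaccharide range 2 of 3 with each sugar.

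**Figure D2:**
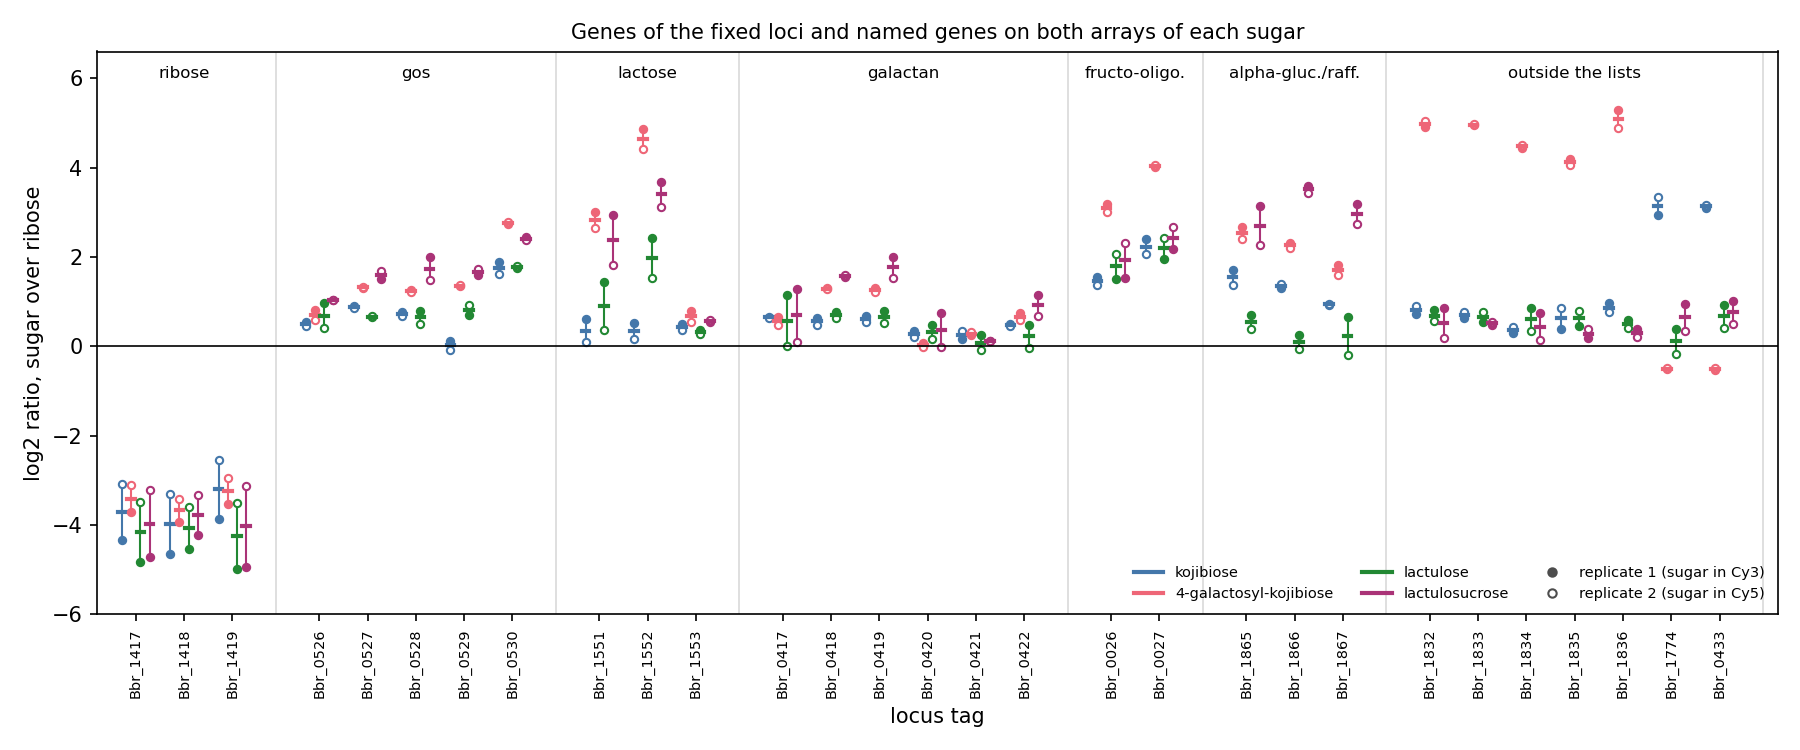
Log2 ratio of sugar over ribose on both arrays for genes of the 6 ranges and some outside them, with filled points for replicate 1 (sugar in Cy3), open points for replicate 2 (sugar in Cy5) and a bar at the mean. The genes Bbr_1832 to Bbr_1836 stand above 4.05 on both 4-galactosyl-kojibiose arrays, and Bbr_1417 to Bbr_1419 lie far below 0 with every sugar.

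The comparison of 4-galactosyl-kojibiose with kojibiose sets side by side 2 sugars that differ by a galactosyl residue. Their arrays also differed in signal. In the sugar channel 61.4% and 47.7% of gene spots were well above background with 4-galactosyl-kojibiose, against 99.99% with kojibiose. The larger sugar had higher Bbr_1832 to Bbr_1836, higher Bbr_1552, 2 of 5 gos genes higher (4 with the replicate number in the fit), and lower Bbr_1774 and Bbr_0433. By limma on the same slide's sugars, 263 genes differed (177 higher, 86 lower), 31 of them over 3-fold (19 without kojibiose replicate 2). Bbr_1836 was higher by 4.22 (95% CI 3.78 to 4.66, adjusted p 4.96e-05) and Bbr_1552 by 4.30 (3.49 to 5.11, adjusted p 0.000627). Bbr_1774 was lower at -3.64 (-4.29 to -2.995, adjusted p 0.000524) and Bbr_0433 at -3.63 (-4.19 to -3.08, adjusted p 0.000209). These 4 differences passed in every alternative run. Bbr_0529 was higher by 1.34 (0.98 to 1.71, adjusted p 0.00327), but not without kojibiose replicate 2 (0.0544) or 4-galactosyl-kojibiose replicate 1 (0.0504). Bbr_0530 was higher by 1.00 (adjusted p 0.00939), but not without kojibiose replicate 2 (0.0987) or 4-galactosyl-kojibiose replicate 1 (0.101) or 2 (0.101). The gos list shifted up (0.0133, and 0.16 with an estimated correlation), with 3 of 5 genes past the test adjusted over the list alone. The count was 852 with slide 1 alone and 596 with the replicate number in the fit. It fell to 45 and 28 without kojibiose replicate 1 and 2, and to 29 and 40 without 4-galactosyl-kojibiose replicate 1 and 2. No difference was detectable for Bbr_1417 (0.30, -1.28 to 1.87).

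The comparison of lactulosucrose with lactulose sets side by side 2 sugars that differ by a glucosyl residue. Bbr_1866 and its neighbours were higher with lactulosucrose. By limma, 89 genes differed (80 higher, 9 lower), 8 of them over 3-fold and all 8 higher. Over 3-fold there were 4 genes without either kojibiose array, and 14 higher and 1 lower without lactulosucrose replicate 1. Bbr_1866 was higher (adjusted p 0.000259) and passed in every alternative run, but its size cannot be given, because its sugar channel with lactulose and its ribose channel with lactulosucrose were not well above background. Bbr_1867 was higher by 2.74 (95% CI 2.05 to 3.42, adjusted p 0.00951), but not without kojibiose replicate 1 or 2 (0.0509 each), nor with slide 2 alone (0.176). Bbr_1865 was higher by 2.16 (adjusted p 0.0156), but not without either kojibiose array (0.0577 each), either 4-galactosyl-kojibiose array (0.0586 each) or lactulose replicate 1 (0.0698) or 2 (0.0657). The gos list shifted up (0.000558, and 0.0706 with an estimated correlation), with 4 of 5 genes past the test adjusted over the list alone. Bbr_1552 was higher by 1.42 without passing (0.0619), and passed with the replicate number in the fit (0.00191) and without background correction (0.0435). Slide 2 alone gave 1 gene, and the fit with the replicate number 297 (227 higher, 70 lower). The count fell to 4 without either kojibiose array, 8 without either 4-galactosyl-kojibiose array, 9 and 11 without lactulose replicate 1 and 2, and 50 without lactulosucrose replicate 1. The kojibiose and 4-galactosyl-kojibiose arrays do not enter this difference. Leaving one of them out changed only the pooled spread and its degrees of freedom, not the log2 values. Bbr_1836 did not detectably differ (-0.21, -0.66 to 0.23).

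The other 4 pairs compare sugars on different slides, so their counts can hold differences between slides. Bbr_1836 and Bbr_1774 also differed between the sugars of slide 1, by 4.22 and -3.64, which a shift common to that slide cannot account for. In the cross-slide differences of these genes and of Bbr_0285, slide and sugar pair cannot be told apart. Lactulose and lactulosucrose both had lower Bbr_1774 than kojibiose and lower Bbr_1836 than 4-galactosyl-kojibiose. By limma, 281 genes differed between lactulose and kojibiose (107 higher, 174 lower), 193 between lactulosucrose and kojibiose (113 higher, 80 lower, and 16 and 7 over 3-fold), 350 between lactulose and 4-galactosyl-kojibiose (81 higher, 269 lower) and 168 between lactulosucrose and 4-galactosyl-kojibiose (56 higher, 112 lower). Over 3-fold were 26, 23, 49 and 32, and leaving out 1 array gave 11 to 40, 11 to 32, 33 to 64 and 17 to 39. With the replicate number in the fit the counts were 691, 516, 745 and 373. Bbr_1774 was lower with lactulose than with kojibiose at -3.03 (95% CI -3.68 to -2.38, adjusted p 0.00226), and with lactulosucrose at -2.49 (adjusted p 0.00344), the latter not without kojibiose replicate 2 (0.0522). Bbr_0285 was higher with lactulosucrose than with kojibiose by 2.09 (1.64 to 2.54, adjusted p 0.00208) and than with 4-galactosyl-kojibiose by 1.98 (1.53 to 2.43, adjusted p 0.0023). Bbr_1836 was lower than with 4-galactosyl-kojibiose at -4.58 with lactulose (-5.02 to -4.14, adjusted p 4.2e-05) and -4.80 with lactulosucrose (-5.24 to -4.36, adjusted p 3.06e-05). The gos list was higher with lactulosucrose than with kojibiose (0.000241, and 0.0594 with an estimated correlation).

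Those counts moved with single arrays and their splits with the processing or an array. Arrays of a sugar outside a pair acted only through the pooled spread and its degrees of freedom. Median centring gave 29 higher and 22 lower between lactulose and kojibiose, the fit with the replicate number gave 252 higher and 264 lower between lactulosucrose and kojibiose, and the Feature Extraction ratios gave 87 higher and 77 lower between lactulosucrose and 4-galactosyl-kojibiose. Between lactulose and kojibiose they were 19 and 17 without kojibiose replicate 1 and 2, 93 without either 4-galactosyl-kojibiose array, 79 without lactulose replicate 1, and 456 without either lactulosucrose array. Between lactulosucrose and kojibiose they were 22 and 17 without kojibiose replicate 1 and 2, and 53 without either 4-galactosyl-kojibiose array, and without lactulosucrose replicate 2 the genes over 3-fold were 13 higher and 19 lower. Between lactulose and 4-galactosyl-kojibiose they were 58 and 47 without 4-galactosyl-kojibiose replicate 1 and 2, 194 without either kojibiose array, and 134 without lactulose replicate 1. Between lactulosucrose and 4-galactosyl-kojibiose they were 26 and 21 without 4-galactosyl-kojibiose replicate 1 and 2, and 106 without either kojibiose array.

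The responses to the sugars shared many genes. Between 4-galactosyl-kojibiose and kojibiose, 161 genes were higher with both and 193 lower with both. Between lactulosucrose and lactulose the shared genes were 198 higher and 284 lower. In the cross-slide pairs the shared higher genes numbered between 129 and 205 and the shared lower genes between 178 and 276. These lists are not independent, since a gene has the same SE with every sugar and ribose RNA may have been shared, so no chance level is given. The log2 ratios of arrays with different replicate numbers correlated across genes between 0.538 (lactulosucrose and kojibiose) and 0.643 (lactulosucrose and lactulose), with a mean of 0.613 over the 6 pairs, where genes are not independent replicates. Ratios were also simulated with no response and with ribose RNA shared by arrays of the same replicate number. Their group means correlated between 0.492 and 0.500, against 0.642 to 0.836 for the group means in the data. The covariance of the group means was at least 0.257 in the data and at most 0.0210 in that simulation. Between arrays with different replicate numbers it was at least 0.237 in the data. The simulated ribose spread came from the difference between replicates, which leaves out ribose RNA common to both replicates. The simulation therefore cannot say how much of the shared response a shared ribose RNA could give.

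**Figure D3:**
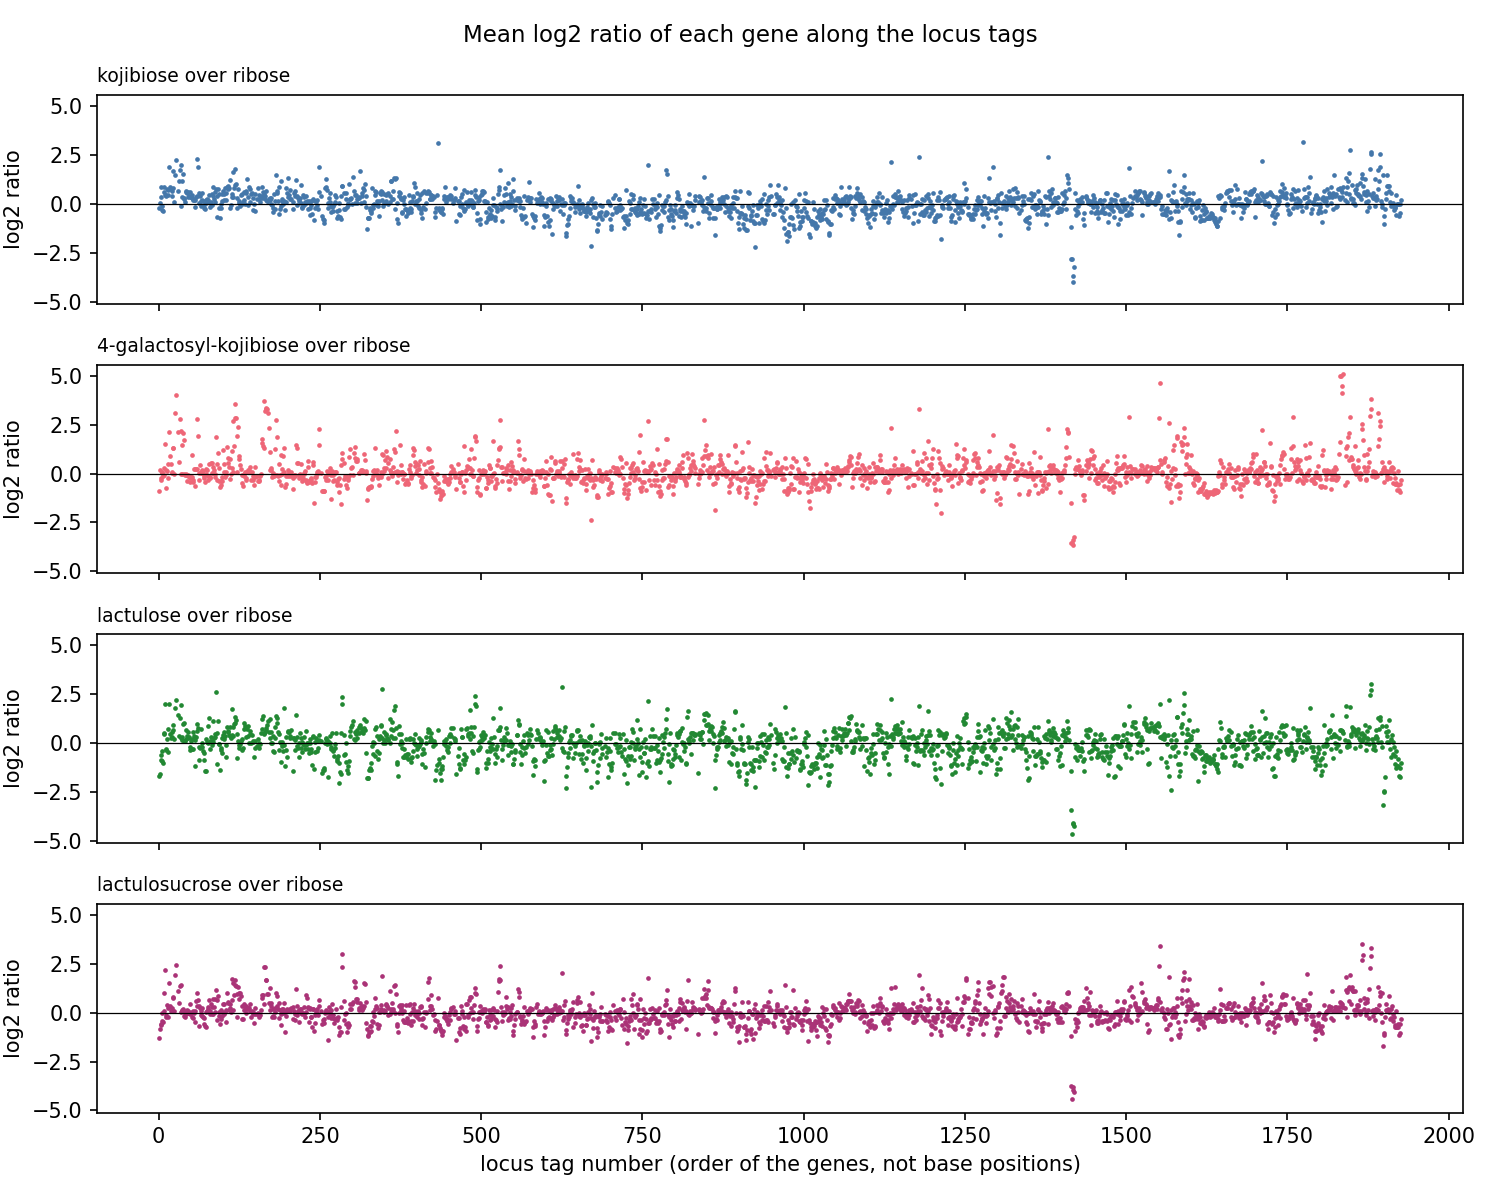
Mean log2 ratio of sugar over ribose of each gene against its locus tag number, with 1 panel per sugar. The fall around Bbr_1417 appears in all 4 panels, and the rise at Bbr_1832 to Bbr_1836 stands out with 4-galactosyl-kojibiose.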

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

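The limits that picked these results, a log2 ratio beyond 1 in opposite directions with 2 sugars, and a called change over 3-fold of a ribosomal or transfer RNA feature whose signal stayed more than 2 times above the negative controls in every channel, were chosen only after the values were seen.

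The arrays carry 47 features outside the 1843 genes that could be tested, among them a probe set for 16S ribosomal RNA. In this data no comparison of the report uses, rRNA16s was higher than on ribose with 4-galactosyl-kojibiose at 1.59 (limma adjusted p 0.00956, replicates at 1.80 and 1.39) and with lactulose at 2.21 (adjusted p 0.00174, replicates at 1.85 and 2.57). With kojibiose it stood at 0.73 (adjusted p 0.128) and with lactulosucrose at 0.54 (adjusted p 0.268), without passing. The 26 plasmid, spike and other features, which lie outside the genes tested, also had medians above 0 on the same sugars, 0.46 with 4-galactosyl-kojibiose (0.82 on replicate 1 and 0.11 on replicate 2) and 0.50 with lactulose, against -0.08 with kojibiose and 0.04 with lactulosucrose. Their lowest signals were 0.731 to 1.02 times the negative controls, so these are largely ratios of background. No explanation was tested, and a ratio within an array does not show which channel moved.

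A pair of genes moved in opposite directions with different sugars, with the difference tested by limma. Bbr_0549 was higher with kojibiose (1.27) and lower with lactulose (-1.08), a difference of -2.35 (adjusted p 0.00226). Bbr_1898 was higher with kojibiose (1.48) and lower with lactulose (-3.17), a difference of -4.66 (adjusted p 0.00226). It was also lower with lactulosucrose (-1.68), a difference from kojibiose of -3.16 (adjusted p 0.00441), which did not pass without kojibiose replicate 1 (0.0618) or 2 (0.0562). Kojibiose and the other sugars of these pairs were on different slides, so slide and sugar cannot be told apart, and the response to different sugars remains open as an untested biological explanation.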

How the results depend on the processing

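Every alternative here was planned, so no test in this part was chosen after its result was seen. Except where noted, the cause of a change was not tested.

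Of the 227 results for named genes (208 called), leaving out 1 array kept 1491 comparisons of call and direction, weakened 318 below the limit and strengthened 7. The other settings kept 2340, weakened 206, strengthened 25 and reversed 3. For named genes this tally held the adjusted p limit at 0.05 in every setting, so the stricter limit of 0.01 was not tested in it. Calls between these limits by limma count as kept there but fail at 0.01. Examples are Bbr_0526 with kojibiose (adjusted p 0.0360) and Bbr_1865 between lactulosucrose and lactulose (0.0156). For the list shifts, leaving out 1 array kept 304 and strengthened 16, and the other settings kept 396, weakened 23, strengthened 20 and reversed 1.

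Leaving out 1 array gave between 196 and 825 genes with kojibiose, 239 and 767 with 4-galactosyl-kojibiose, 579 and 1148 with lactulose, and 417 and 593 with lactulosucrose. Over 3-fold the ranges were 34 to 47, 82 to 90, 80 to 153 and 49 to 68. For differences they were 28 to 368 (4-galactosyl-kojibiose against kojibiose), 4 to 99 (lactulosucrose against lactulose), 17 to 456 (lactulose against kojibiose), 17 to 242 (lactulosucrose against kojibiose), 47 to 463 (lactulose against 4-galactosyl-kojibiose) and 21 to 196 (lactulosucrose against 4-galactosyl-kojibiose). The list shifts past the test were 14 to 15.

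Without background correction the genes over 3-fold were 26 with kojibiose, 44 with lactulose and 31 with lactulosucrose, and 259 genes differed between lactulosucrose and 4-galactosyl-kojibiose. With the Feature Extraction ratios 148 genes changed with kojibiose, 23, 168, 308 and 159 were over 3-fold with the 4 sugars in order, and 106 differed between 4-galactosyl-kojibiose and kojibiose. There the range Bbr_1855 to Bbr_1869 turned to higher in lactulosucrose than kojibiose (adjusted p 0.00529). That setting moved the median of all genes from 0.02 to -0.09 with 4-galactosyl-kojibiose and from 0.01 to -0.10 with lactulose.

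With median centring 115 genes were over 3-fold with kojibiose, and 17 differed between lactulosucrose and lactulose, 51 between lactulose and kojibiose and 87 between lactulosucrose and 4-galactosyl-kojibiose. With kojibiose it turned Bbr_0527 to -0.11, Bbr_0528 to -0.093 and Bbr_0419 to -0.17. Scaling between arrays gave 146 genes over 3-fold with 4-galactosyl-kojibiose, 670 changed and 27 over 3-fold with lactulose, 12 differing between lactulosucrose and lactulose and 89 between lactulose and kojibiose. The mean over probes gave 291 genes differing between lactulosucrose and kojibiose.

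The replicate number in the fit gave 888 genes with lactulosucrose and 596, 297, 691, 516, 745 and 373 differences in the order above. Slide 1 alone gave 1170 genes with kojibiose, 1042 with 4-galactosyl-kojibiose and 852 differences, and slide 2 alone gave 604 with lactulose, 231 with lactulosucrose and 1 difference. The 2 arrays of a sugar alone gave 1163 (kojibiose), 1062 (4-galactosyl-kojibiose) and 269 (lactulosucrose). By construction an adjusted p limit of 0.01 gave fewer, 354, 409, 634 and 307 against ribose and 72, 11, 65, 41, 112 and 70 for the differences.

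With the estimated correlation 1 of the 14 list shifts passed. The mean correlation between sugars, 0.613, was 0.686 with the same replicate number and 0.702 with group means. The study's regularised t-test with its ratio limits gave 43, 88, 96 and 49 genes on the values normalised here, and 27, 174, 253 and 92 on the Feature Extraction ratios, which are those of the deposited tables. The deposited tables hold no p-values, so that alternative was not run. Signal over background limits dim genes with 4-galactosyl-kojibiose and lactulose.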

Other observations

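Only the test of a single array or dye orientation for Bbr_1832 to Bbr_1836 was chosen after its result was seen, and the runs and non-gene features were described without a test planned for them.

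Arrays with the same replicate number deviated together from the means of their sugars, with both sugars of a slide and across slides. Dye bias of single probes would not be shared by neighbouring genes, yet the deviation, with its trend on signal removed, correlated at 0.330 (bootstrap SE 0.0256) across 1778 pairs of adjacent locus tags, against at most 0.0705 in 1000 shuffled orders. That exceeds the limit of 0.3 set for the test by little more than 1 SE, and adjacent genes can share base composition, so it argues against bias of single probes as the whole source and not against every dye effect. A different state of the cultures in the replicate rounds would put the deviation between genes, and the share of the probe-level variance between genes was 0.393, which lay between the limits and does not decide it. Replicate number and dye orientation cannot be told apart in this design.

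The rise of Bbr_1832 to Bbr_1836 with 4-galactosyl-kojibiose was weighed against technical sources. The lowest of its 10 log2 ratios was 4.05, so neither 1 array nor 1 dye orientation makes it. On replicate 2 the ribose channel of these genes was not well above background, and on replicate 1, where it was, the lowest was 4.19. The ribose-channel level on those arrays was 0.272 above that on the other 6, while the sugar channel was 4.39 above. The ratio thus rose through the sugar channel and not through a ribose level lower than on the other arrays. A dim ribose channel leaves little room for a much lower level. The values therefore cannot say how far a dim ribose channel shaped the size of the folds. Of the 24 probes of the 5 genes, 100% were over 3-fold on both arrays, which argues against cross-hybridisation of single probes. The genes were picked by medians over these probes, so a low share was improbable beforehand, but a median leaves room for low probes and none was seen. A response of the cells to this sugar remains open and was not tested apart from these.

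Each lactulosucrose array resembled the same-numbered lactulose array (0.838 and 0.822, across genes) more than its own replicate (0.686). Swapped labels in 1 replicate would turn the sign of the difference between these sugars between replicates, but that difference correlated at 0.793 between them, which argues against a swap. Regressing out the deviation measured on the other slide raised the correlation of the lactulosucrose arrays by 0.0903, from 0.686 to 0.776. The lactulosucrose deviation was already known to correlate with those of kojibiose (0.577) and 4-galactosyl-kojibiose (0.451). A rise was therefore likely beforehand. It gives the size of the part shared with the other slide and is not separate support for a shared deviation.

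Genes over 3-fold often lay side by side. In runs of at least 3 adjacent tags changed in the same direction stood 8 genes with kojibiose, 36 with 4-galactosyl-kojibiose, 21 with lactulose and 22 with lactulosucrose, against at most 3, 7, 6 and 3 in 1000 shuffled orders.

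Of 20 transfer RNA features, 12 were higher with kojibiose, 0 with 4-galactosyl-kojibiose (2 lower), 5 with lactulose (2 lower) and 8 with lactulosucrose by limma, with medians of 0.62, -0.07, 0.02 and 0.52. Apart from tRNA-Gln (3.48) and tRNA-Glu (7.24), the lowest signal of each was under 2 times the negative controls, down to 0.920 for tRNA-Ser, so these counts and medians rest mostly on dim features. The largest rises were those of tRNA-Asn (2.37, adjusted p 0.000356) and tRNA-Asp (1.73, adjusted p 0.000486) with kojibiose, both among the dim features.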
